A study of Capra hircus with 12 samples.

How the data were processed

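Whole blood RNA of 12 Carpathian goats, 6 with low and 6 with high proviral load, was measured by single-end RNA sequencing over 50 cycles. Per the labels' protocols, RNA was isolated from stabilised blood with a MagMAX kit and treated with DNase. It was used where its integrity number was above 8, and libraries were made from 300 ng of total RNA with a TruSeq RNA v2 kit. That kit does not mark strand, so reads of overlapping genes on opposite strands cannot be told apart. The deposited files hold raw read counts per Ensembl goat gene identifier, 1 file per goat, with no normalization. FastQC, TopHat, HTSeq and DESeq2 are named in the submitters' processing notes, without versions or settings. The genome build, annotation release and counting options are not given in the sources used here.

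Each deposited file lists counts for 27271 gene identifiers and 5 HTSeq summary lines that name no gene. The latter stayed out of library sizes and tests. Of all records in a file, 31.2% to 36.6% were assigned to no feature, and 0.597% to 1.34% overlapped several genes. Whether some of those without a feature lay within genes is not known, since the counting options are not given. At least 13.8% (low 12) were counted as aligned at more than 1 place. Records aligned at several places are not in the gene counts, so genes with near-identical copies are under-counted and their values uncertain.

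None of the identifiers matched the gene table used here, of assembly ARS1.2 (0 of 27271). Symbols, functions and positions are therefore not used, and genes are given by identifier. Tests and scores of 30 gene lists fixed by symbol, among them leukocyte markers, interferon-stimulated genes and restriction factors, had been planned and were not run, nor were the values of 10 single genes fixed by symbol. The rule for named genes, set before the data were examined, prints at most 2 identifiers higher and 2 lower, those with the smallest p, for genes without a symbol. The parts of that rule that need symbols could not be used.

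The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) of high minus low proviral load on the deposited counts, with all 12 samples and no covariate. Genes were kept by filterByExpr with a minimum count of 10, which left 12941 of the 19671 with any read. TMM factors and a robust fit were used, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 95% intervals come from the unshrunk coefficient and its SE. CPM values were scaled by TMM factors, and log2 CPM used a prior count of 2. Single values per library were compared by two-sided exact permutation over all 924 assignments of goats to groups. Replicates are separate goats, and the labels give no batch.

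Reads assigned to genes ran from 6894973 to 19204978 per library. The level that a count of 0 allows is 3 counts of the library size scaled by its TMM factor. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules.

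The scripts were tested on simulated data before use. Counts were drawn for the 12941 filtered genes from the real means, dispersions and library sizes. Between 6 and 6 samples, 100 genes were changed 2-fold and 100 changed 4-fold. The filter was applied again and left 12879 genes, and a changed gene lost there counted as not recovered. EdgeR recovered 25% and 78% of the changed genes, with 4 calls among unchanged genes, and limma-voom with sample quality weights 21% and 72%, also with 4. Each gene was drawn independently, with no axis of variation shared between samples. The 4 calls therefore do not measure false calls of either method in the real data.

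Alternatives set before the data were examined were DESeq2 size factors and upper-quartile factors in edgeR, no filter, a minimum of 1 CPM in 6 samples, limma-voom with sample quality weights (limma 3.58.1), a non-robust fit, DESeq2 (version 1.42.0), an adjusted p under 0.1, a change of at least 1.5-fold, and leaving out each goat. After the data were seen, further alternatives were added: principal components, surrogate variables (sva 3.50.0) and the share of multiply aligned records as covariates, a block by that share, thinned reads, other sample weights, the 100 most abundant genes left out, and several libraries left out together. Numbers of calls by edgeR and by limma-voom with quality weights were also counted in 100 of the 462 splits of the goats into groups of 6, the real one included.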

Results

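The study asked which transcripts in blood go with proviral load, the amount of viral DNA integrated in the host genome, in goats infected with small ruminant lentiviruses. These retroviruses include the agent of caprine arthritis-encephalitis. Whole blood RNA was sequenced from 12 female Carpathian goats, 6 with low and 6 with high proviral load, with 1 library per goat. Each goat is named here by its group and its number in the labels. The goats had been selected by provirus copy number, so the groups were not random draws. The copy numbers of single goats were not analysed here.

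Reads assigned to genes averaged 15333581 ± 2738878 per library in the low group and 14042367 ± 5059372 in the high group (SD, n = 6 each). The groups were not separated by this measure (two-sided exact permutation p = 0.600). The libraries with the fewest reads were high 27 with 6894973, high 6 with 8430250 and low 15 with 11010428. Of 27271 annotated genes, between 12538 (high 27) and 16834 (low 30) had at least 1 read. The mean difference in detected genes, high minus low, was -402 (two-sided exact permutation p = 0.701). A count of 0 allowed a level of up to 0.131 CPM (the read count scaled to library size) in the deepest library and 0.583 CPM in high 27.

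**Figure D1:**
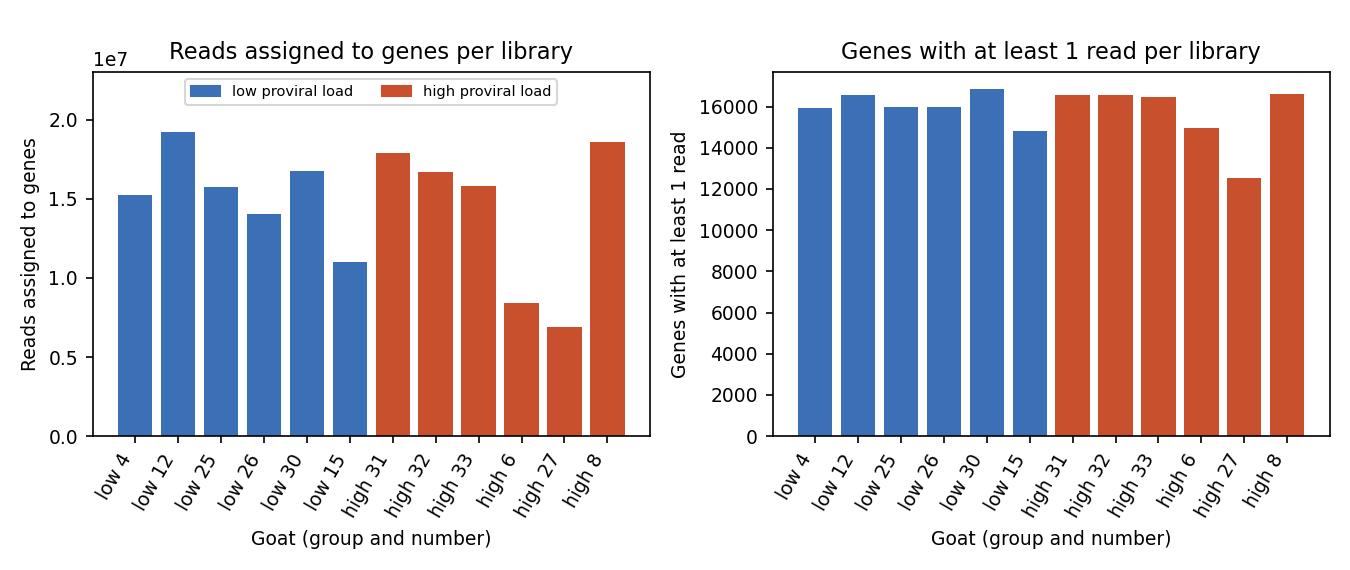
Bars give the reads assigned to genes (left) and the number of genes with at least 1 read (right) in each of 12 goats, with low proviral load in blue and high in orange. High 27 and high 6 had the fewest reads, at 6894973 and 8430250, and high 27 had the fewest detected genes, at 12538.

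The comparison of high with low proviral load found no gene that differed between the groups. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 12941 tested genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.9999. At an unadjusted p under 0.05 there were 317 genes, 94 higher and 223 lower in high-load goats, where evenly spread p-values would give 647. In 63 of 100 splits of the goats into 6 and 6, the real one included, at least as many genes reached this p. The median of the other splits was 433, so evenly spread p-values are a poor reference here. Leaving out 1 goat gave between 206 and 607 genes. The lean towards lower values depended on the setting: the split was 118 higher and 175 lower with upper-quartile factors, 185 and 165 without high 6, and 347 and 351 with no filter. DESeq2, run without the low-count filter on 19616 genes, called 0 genes, with 624 at an unadjusted p under 0.05 and a smallest adjusted p of 0.160. Of 36 alternative settings, 5 called any gene. The most calls came from limma-voom with sample quality weights, which gives less weight to libraries that fit the model poorly: 17 genes, 2 higher and 15 lower in high-load goats. Without those weights limma-voom called 0 genes. With them, leaving out 1 goat gave between 0 and 601 calls. In 7 of 100 splits of the goats, the real one included, there were at least 17.

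**Figure D2:**
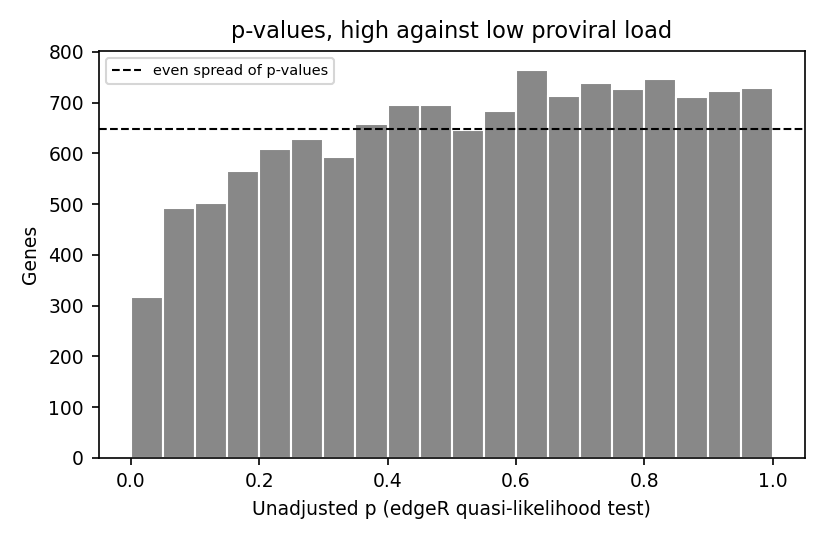
Number of genes in 20 equal bins of the unadjusted p from edgeR's test of high against low proviral load, over 12941 genes. The first bin holds 317 genes, and the dashed line marks the 647 per bin of evenly spread p-values.

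The genes with the smallest p in each direction did not pass the threshold and are described by their values. ENSCHIG00000015079 had 6.33 ± 1.45 CPM in high-load and 11.5 ± 1.84 CPM in low-load goats (SD, n = 6 each). Its values were lower in 6 of 6 high-load goats than in any low-load goat. The log2 fold change was -0.84 ± 0.21 (SE), with a 95% interval from -1.29 to -0.40 and an adjusted p of 0.9999 in edgeR. ENSCHIG00000021234 had 0.779 ± 0.555 CPM in high-load and 4.10 ± 2.62 CPM in low-load goats, a log2 fold change of -2.52 ± 0.64 (SE; edgeR adjusted p = 0.9999). Its values lay below the low-load median in 6 of 6 high-load goats and below every low-load goat in 2 of 6. The counts were 3 to 14 reads per high-load library and 11 to 119 reads per low-load library.

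In the other direction, ENSCHIG00000007585 had 1.16 ± 0.604 CPM in high-load and 0.257 ± 0.173 CPM in low-load goats (SD, n = 6 each), a log2 fold change of 1.97 ± 0.54 (SE; edgeR adjusted p = 0.9999). ENSCHIG00000014847 had 1.54 ± 1.08 CPM in high-load and 0.379 ± 0.258 CPM in low-load goats, a log2 fold change of 1.90 ± 0.54 (SE; edgeR adjusted p = 0.9999). For both genes the values of 6 of 6 high-load goats lay above those of every low-load goat. ENSCHIG00000007585 rested on 7 to 21 reads per high-load library and 0 to 9 per low-load library, and ENSCHIG00000014847 on 10 to 26 and 1 to 13. The count of 0 for ENSCHIG00000007585, in low 15, allowed up to 0.381 CPM. High 27 had the highest value of both genes. All 4 genes were picked for their small p among 12941, so the separation of their values is not independent evidence of a difference.

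**Figure D3:**
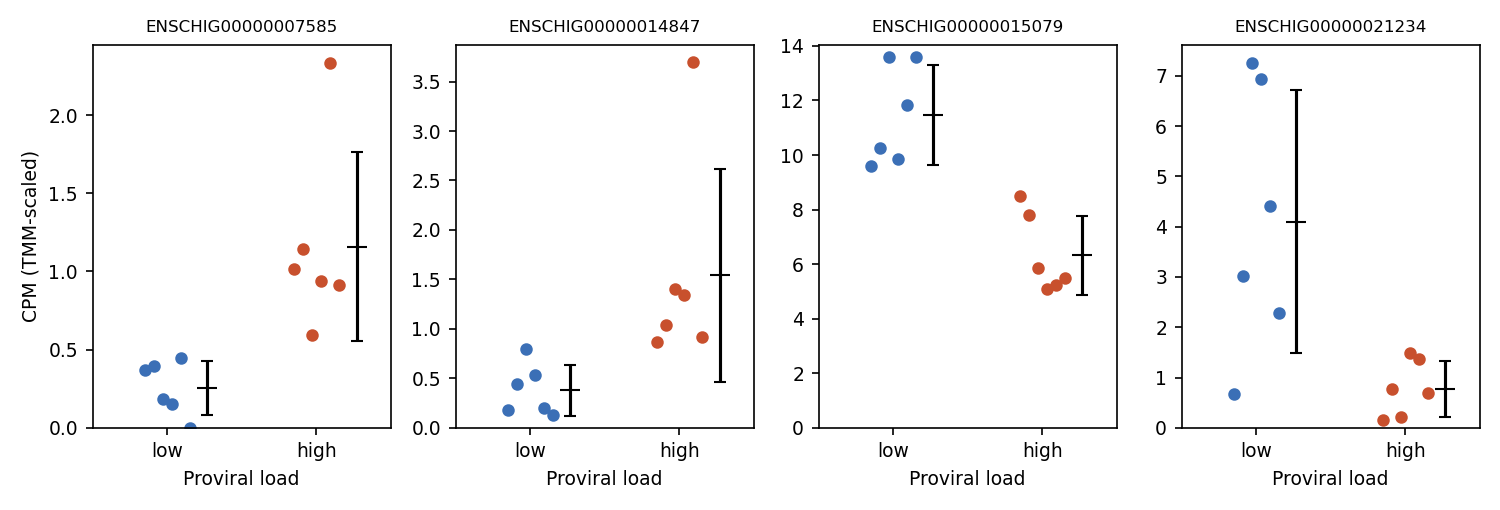
CPM scaled by TMM factors in each goat for the 4 genes named by smallest p, with the mean and SD (n = 6) beside each group, low-load goats in blue and high-load goats in orange. None of the 4 passed the adjusted threshold, and in ENSCHIG00000021234 the groups overlap.

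Over all tested genes, the values of the groups did not overlap in 20 genes, 5 higher and 15 lower in high-load goats. A random assignment of goats to groups gives 0.216% of genes on average, or 28.0 of 12941. That mean is raised by a few splits with many genes: the median of the other splits was 14 and the highest 862. Fewer goats raise that share: leaving out 1 goat gave between 22 genes (without low 25) and 84 (without low 15). There were 72 without low 12 and 68 without high 27. Chance then gives about 56.6 on average, and the median of the other splits lay between 29 and 34. Without high 6 and high 27 there were 288 genes, 134 higher and 154 lower, where chance gives 0.952% or 126 genes on average. The median of the other splits was 76 and the highest 1583. Without low 15 as well there were 464, where chance gives 209.6 on average and the median of the other splits was 128. High 6 and high 27 were left out after they were seen to stand apart. That narrows the high group and can raise the count by itself, so the chance values are no fair reference. With all libraries kept and thinned to the smallest total, 8 genes did not overlap.

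Whole-blood profiles did not part by proviral load either. The median Spearman correlation of log2 CPM across genes was 0.939 between pairs of high-load goats, 0.953 between pairs of low-load goats and 0.943 between goats of different groups. Genes are not independent replicates in these correlations. The closest pair was high 31 and high 32, at 0.988, and low 4 was closer to high 32, at 0.981, than to any low-load goat, at most 0.971. The smallest chi-square per degree of freedom between any pair was 23.2, far above sampling noise, so all 12 libraries were kept as separate samples. The first principal component held 42.4% of the variance and the second 14.3%. Scores on the first averaged 5.72 ± 72.5 in the high group and -5.72 ± 33.2 in the low group (SD, n = 6 each; two-sided exact permutation p = 0.857). The exact permutation p was 0.541 on the second component and 0.279 on the third, and the adjusted p was 0.857 for each of 11 library measures tested. High 27 lay apart on the first component, at 151.6, and high 6 on the second, at -79.9.

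**Figure D4:**
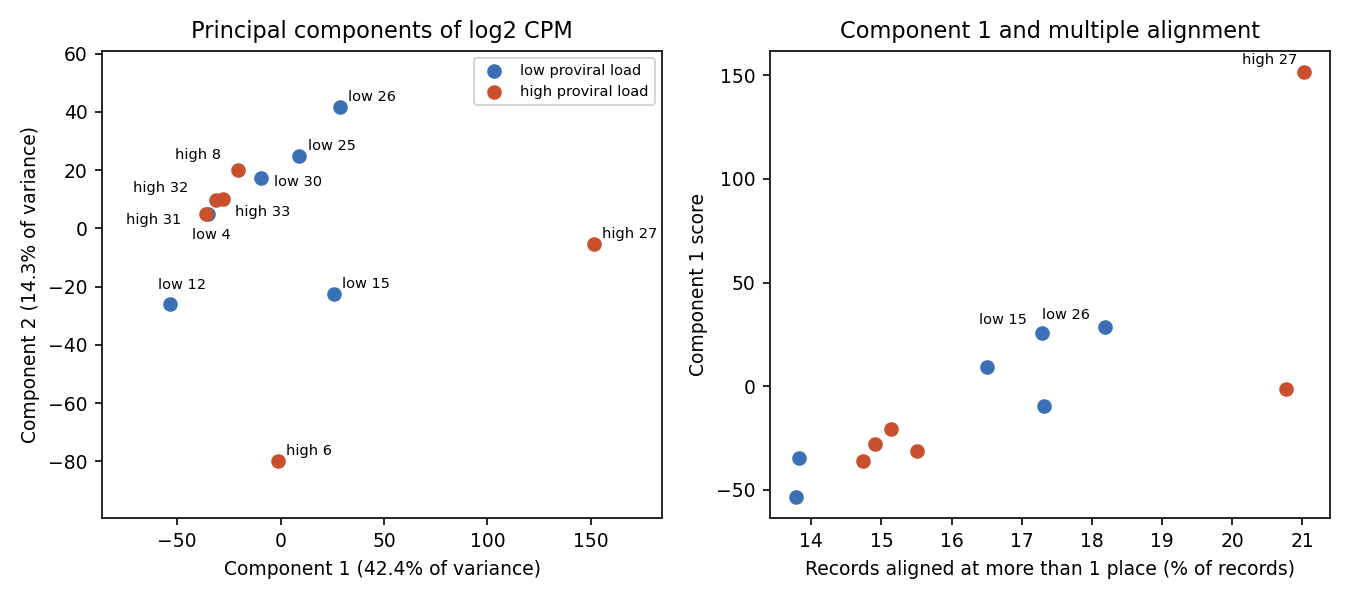
Left, scores of the 12 goats on the first and second principal components of log2 CPM over 12941 genes, and right, the first score against the percentage of records aligned at more than 1 place, with low-load goats in blue and high-load goats in orange. The groups overlap, with high 27 apart at 151.6 on the first component and high 6 at -79.9 on the second.

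The spread between goats did not differ by group when all 12 were used. The median over genes of the SD of log2 CPM was 0.499 in high-load and 0.489 in low-load goats, a log2 ratio of 0.03 (two-sided exact permutation p = 0.922). Without high 6 and high 27 the median SD of the high group was 0.240 and the log2 ratio -1.02, or -0.81 without low 15 as well. The low group also fell, to a median SD of 0.355, without low 15 and low 26. Ratios with libraries left out were not tested, and leaving out libraries that stand apart lowers the spread of their group by construction.

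The data set bounds on the size of the differences. The 95% interval of the fold change lay within 2-fold in either direction for 8054 genes (62.2%) and within 4-fold for 12388 (95.7%), counted per gene with no adjustment for the number of genes. The share within 2-fold was 25.6% in the third of genes with the lowest mean level and 83.5% in the third with the highest. When changes of known size were planted in these counts, with 100 genes for each size, edgeR recovered 21% of 2-fold and 67% of 4-fold changes among 12928 genes. Limma-voom with sample quality weights recovered 56% and 84% of them, with 90 calls outside the planted genes where edgeR made 0. It called 17 genes with nothing planted, and the other genes keep their real counts, so the 90 are not known false calls. Most planted 2-fold differences were thus missed by edgeR with these 12 libraries.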

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

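For high 27, the test against the main axis of the other goats was chosen after the result was seen, and the tests of depth and of abundant genes before. In each group of 6 values, the gap between the most extreme library and its neighbour was set against the range of the group. Of 30 groups of values screened, 6 held a library that stood apart. Chance alone gives about 1 in 20 for independent values. The values screened included principal components, library measures that go together and genes picked for their small p. That rate is therefore no fair reference, and the 6 cannot be read as an excess over chance.

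High 27 stood apart from the other high-load goats on the first principal component, at 151.6, with a gap of 0.814 of the range. Lower depth does not account for this alone: with every library thinned to 6894973 reads the gap was at least 0.7205 in 10 draws, and high 27 had 12538 detected genes against 14466 to 15770 in the other libraries. Without the 100 most abundant genes the gap was 0.8264. A component over the log2 CPM of 12941 genes could hardly move with 100 left out, so this does not decide the part of abundant genes. Across genes, which are not independent replicates, the deviation of high 27 went with the first component of the other 11 libraries (Spearman rho 0.5257). High 27 may thus lie at an extreme of an axis along which the other goats also vary. Sample handling and a difference between goats stay open as untested, its own proviral load included.

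Other values stood apart and were not followed up. High 6 scored -79.9 on the second component. High 8 had 36.6% of records assigned to no feature, and low 15 had 1.34% of records overlapping several genes. High 27 had the highest level of ENSCHIG00000007585, at 2.33 CPM, and of ENSCHIG00000014847, at 3.69 CPM.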

How the results depend on the processing

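Covariates, blocks, thinning, other sample weights, leaving out the 100 most abundant genes or several libraries, leaving goats out of limma-voom, and all alternatives for the spread and for genes without overlap were chosen after the data were seen, the rest before. The count of 0 genes held in 31 of 36 alternatives, including each that left out 1 goat in edgeR (0 to 0 genes). Among them, an adjusted p under 0.1 and a change of at least 1.5-fold reuse the main fit. Their 0 calls followed from its result and add no support. The smallest adjusted p was 0.0141 at its lowest over the 36, and 0.920 at its lowest over those that left out 1 goat. The planned limma-voom with sample quality weights called 17 genes. Of the added settings, edgeR called 1 gene without high 6, high 27 and low 15, 2 genes with 3 surrogate variables, the number estimated from the data, 1 gene with 2 surrogate variables and 2 genes with 4, all lower in high-load goats; with 1 surrogate variable or with 1 to 3 principal components it called 0. The cause was not tested. Surrogate variables were estimated from the same counts with the groups in the model. Treated as known covariates, they can understate the residual variation, and with it p and the width of intervals. No other splits of the goats were run with them. Genes at an unadjusted p under 0.05, 317 with all goats, numbered 607 without low 12, 606 without high 27, 206 without low 25, 944 without high 6 and high 27, 698 with no filter and up to 2341 with 4 surrogate variables; higher genes outnumbered lower ones without high 6 (185 to 165), with the block by multiple alignment (465 to 337) and in limma-voom with quality weights (1248 to 1066). The log2 fold changes of the named genes kept their sign and stayed short of the threshold wherever tested (ENSCHIG00000015079 -0.95 to -0.65, ENSCHIG00000021234 -3.25 to -1.95, ENSCHIG00000007585 1.53 to 2.18, ENSCHIG00000014847 1.31 to 2.25). The share of genes bounded within 2-fold ran from 41.2% with no filter to 80.1% with 4 surrogate variables, and was 62.6% with all libraries thinned to the smallest total against 62.2% at full depth. Detected genes counted from 10 reads differed by -256, high minus low (exact permutation p = 0.589). No paired analysis was possible because the groups share no goat numbers. Alternatives that need gene symbols (neutrophil score as covariate, erythroid genes left out, all gene list tests and scores) were not run.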

Other observations

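In this part, the splits and the weights estimated without the groups for limma-voom, and the tests on the spread and on genes switched on or off, were set before their results were seen; all correlations, the other splits for edgeR and for genes without overlap, the goats left out of limma-voom and the block by multiple alignment were chosen after.

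The first principal component, on which high 27 lay far apart, went with the share of records aligned at more than 1 place. The first principal component rose with that share (Pearson r = 0.789, permutation p = 0.00069; Spearman rho = 0.895, permutation p = 0.00017; n = 12), with adjusted p of 0.00276 and 0.00068 over the 4 library measures tried. Without the 2 libraries farthest from the median share, r was 0.913. Within the high-load goats r was 0.759 (exact permutation p = 0.0125, n = 6) and rho 0.829 (exact p = 0.0583), and within the low-load goats r was 0.912 (exact permutation p = 0.0153, n = 6) and rho 0.829 (exact p = 0.0583). The first component also went with total counts (r = -0.787, permutation p = 0.00155; rho = -0.755, permutation p = 0.00638; adjusted p 0.00310 and 0.00638; r = -0.774 without 2 libraries), with the share of records in genes (r = -0.642, permutation p = 0.0103; rho = -0.790, permutation p = 0.00338; adjusted p 0.0137 and 0.00451; r = -0.638 without 2 libraries) and, by rank, with the share overlapping several genes (r = 0.618, permutation p = 0.0723; rho = 0.853, permutation p = 0.00083; adjusted p 0.0723 and 0.00166; r = 0.696 without 2 libraries). These 4 measures are not separated here.

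Among all 462 splits of the goats into 6 and 6, the most genes without overlap, 862, came with low 25, low 26, low 30, low 15, high 6 and high 27 on one side. The real split gave 20, and 175 splits gave as many, so chance is not excluded for it. Nor is it for the 288 genes without high 6 and high 27, since 18 of the 210 splits of the other 10 goats gave as many, the highest other 1583. Without low 15 as well there were 464, with 13 of 126 splits giving as many. The split with 862 genes was picked as the highest of all 462, and some split must be the highest. Its count therefore does not by itself show a structure of the samples, and no reference for such a maximum was computed. The 6 samples named for that split were also those with the larger share of multiply aligned records, 16.5% or more against 15.5% or less. This was noticed only after the split was found. A test of these samples against the rest was run but is not reported, because they had been picked by their expression and its outcome would be circular. With that share as a block, edgeR called 0 genes between high and low proviral load, with 802 at an unadjusted p under 0.05. Within the 6 samples of larger share (2 high, 4 low) edgeR called 0 of 13093, with 1182 unadjusted. Within the 6 of smaller share (4 high, 2 low) it called 0 of 13612, with 1824. Both unadjusted counts exceed the share of 0.05 that evenly spread p-values give, and no other splits of these sets were run. With 2 goats on one side, 0 calls decides little.

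The 17 genes called by limma-voom with sample quality weights did not stand out from chance: 7 of 100 splits gave as many, the highest other 1829. That split exchanged low 4 and high 27, and edgeR called 0 genes in it; its count may come from a structure of the samples or from the weighting, which no test here separates. The weights ran from 0.208 for high 27 to 4.01 for high 32 and may have been set by the grouping itself. Weights estimated without the groups gave 0 calls, with a smallest adjusted p of 0.0683 and 1089 genes at an unadjusted p under 0.05. These were 0.0141 and 2314 with quality weights, and 0.9999 and 357 with no weights. The fall to 0 calls rests on a threshold and does not decide how far the grouping set the weights. With quality weights, calls numbered 0 without low 25, low 26, low 30, high 31 or high 32, 10 without high 8, 11 without low 15, 17 without high 27, 20 without high 6, 23 without high 33, 472 without low 4 and 601 without low 12. The 15 lower genes, picked for being lower, had a median difference from the low-load median between -3.07 and -2.01 log2 units in high 31, high 32, high 33 and high 8, but -0.05 in high 6 and 0.73 in high 27, while low 4, a low-load goat, was at -1.05.

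For the edgeR count of 0 genes a comparison with other splits decides nothing, since 100 of 100 must give as many; the highest other gave 3. The spread ratio between the groups was at least as far from 0 in 852 of 924 assignments of goats, with 1.101 the highest other. Of 6 genes with at least 5 CPM in 3 or more goats and no read in 3 or more, 0% differed between the groups by Fisher's exact test at p under 0.05, too few genes to decide.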
